A study of Bos taurus with 4 samples.

How the data were processed

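Noncoding transcripts of 4 skeletal muscles of Hereford cattle (longissimus thoracis, a scapula muscle, gluteus and an intercostal muscle) were measured by Illumina sequencing of total RNA. Per the labels' protocols, equal amounts of RNA from 3 animals were mixed into 1 pool per muscle, so each muscle has 1 library, and the animals were 18 months old and kept in a common feedlot. Per the submitters' processing notes, TopHat2 2.0.9, Cufflinks 2.1.1 and the genome build UMD3.1 were used, with no role or order stated. The strand setting of the libraries and of the counting, the filters that made a transcript a noncoding candidate, and the annotation version are not given in the sources used here.

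The deposited tables give 1 FPKM value per transcript and library, made by the authors, and list only values above 0. Each transcript carries an identifier of 8 parts, including a locus, a transcript number, the nearest gene and a Cufflinks class code, which was u (intergenic), i (within an intron) or x (exonic overlap on the opposite strand). The part that holds the exon number was 1 for every transcript. No coordinates are given, so transcripts are described by gene and class, and none was placed on a chromosome. Protein-coding genes were not analysed here, so the planned comparisons of noncoding with coding levels and of their muscle specificity were not made, and medians per class are given in their place. Of 6589 nearest gene names, 312 were Ensembl identifiers and 5994 were found in the RefSeq gene table of assembly ARS-UCD2.0, 5961 of them as protein-coding genes. That table was used for names only, since its build differs from the authors'.

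Read numbers were recovered from the FPKM values deposited by the authors. For each library a total was found at which all values equalled a whole number of reads over a whole length, with a relative error under 1e-11 for all 115374 values. The totals were 2132255 reads for longissimus thoracis, 1511933 for the scapula muscle, 1107493 for gluteus and 1318644 for intercostal muscle. The recovered reads summed to 99.0%, 100.01%, 103% and 101% of these totals in the same order, so the values are scaled to a total close to the reads in the listed transcripts, and what that total counts is not given in the sources used here. The recovered read numbers and lengths are the smallest that give the value, so they are lower bounds and the intervals made from them are at their widest. Lower bounds that sum to more than a total mean that it did not count each of these reads once. A read may therefore be counted in more than 1 transcript. The median listed transcript had 16 reads in longissimus thoracis, 11 in the scapula muscle, 10 in gluteus and 11 in intercostal muscle. Transcripts with 1 read made up 6.36%, 10.9%, 12.4% and 11.1% of those listed. One read on a transcript of 300 nucleotides is worth 1.56, 2.20, 3.01 and 2.53 FPKM in the same order.

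Levels were compared as log2(FPKM + 1), with a transcript that is not listed entered as 0 in counts, correlations and list medians. A fold change on this scale understates the difference of low transcripts. A transcript was detected at 0.1 FPKM or more. It was called higher or lower in a muscle where log2((FPKM + 1)/(median of the other 3 + 1)) was at least 1 in size, that is 2-fold, with 1 FPKM or more in at least 1 library. Pairs of muscles were compared by the same size rule. These calls are a rule of size and not a test, and no p-values were computed. The counts that counting noise alone would give came from 50 draws of Poisson reads with the same rate in every library, over all transcripts and over those listed in every muscle in the data. Correlations are Pearson's r and Spearman's rank correlation across transcripts. The specificity index tau was computed on log2(FPKM + 1). Intervals of the ratios at marker lists come from 10000 draws of a list's transcripts with replacement. Intervals of FPKM are exact Poisson intervals at 95%, and those of shares of reads are Wilson intervals.

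The 21 gene lists were fixed before the data were examined. They are slow-twitch fibre, fast-twitch fibre, glycolysis, fatty acid oxidation, nuclear oxidative phosphorylation, mitochondrially encoded, ribosomal protein, immediate early and stress, atrophy and autophagy, position identity, imprinted growth, interferon and known long noncoding RNA genes, and markers of adipocytes, fibroblasts and matrix, endothelium, smooth muscle and pericytes, leukocytes, erythroid cells, nerve and Schwann cells, and satellite cells. Each list was measured through the transcripts whose nearest gene is a member, and the 16 lists with at least 5 transcripts were compared. The median log2 ratio was placed among 10000 random lists of the same size matched on mean level in 20 bins, but not on gene or class. Medians outside percentiles 2.5 to 97.5 were called.

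The rule for named genes was also fixed before the data were examined. Per muscle it takes the 10 highest and 10 lowest ratios among transcripts with a gene symbol, kept only where the muscle lies beyond each of the other 3. It also takes up to 4 members per list and muscle with the most abundant member, the largest ratio of each pair of muscles, the 5 transcripts of highest mean level and the 3 highest ratios per muscle. A further 33 transcripts, and antisense transcripts with 60 or more reads in a library ranked by ratio, were chosen after their values were seen, as were the groups of small RNA genes.

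The steps were tested on simulated data. Reads were drawn for the 63845 transcripts with 200 of them changed by known folds. In longissimus thoracis 58% of the transcripts raised 2-fold were called higher, 94% of those raised 4-fold and 100% of those raised 8-fold. The shares were 40%, 90% and 100% in the scapula muscle, 34%, 84% and 100% in gluteus and 36%, 88% and 99% in intercostal muscle. Of unchanged transcripts 11.8%, 10.9%, 10.5% and 10.8% were called higher in the same order, so many of the called transcripts with few reads can come from counting noise. Recovery of reads from simulated FPKM returned 96.4% of the read numbers exactly over the 7188 transcripts listed in every library, and 4 of 4 totals. Transcripts listed in fewer libraries were not simulated, and fewer values set their lengths and read numbers.

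Alternatives planned before the data were examined covered the detection limit, a pseudocount of 0.1 FPKM, rescaling by the median ratio, filters at 0 and 5 FPKM, a call beyond each other muscle, the mean log2 reference and list members at 1 FPKM or more. Added after seeing the data were sums per locus, thinning of reads to the smallest total, a minimum of 10 reads in a library, leaving out the longissimus thoracis library, and leaving out the transcripts opposite COL3A1 and COL5A2 from the fibroblast list. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.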

Results

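Noncoding candidate transcripts were measured by Illumina RNA sequencing in 4 skeletal muscles of Hereford cattle. The muscles were longissimus thoracis (a muscle of the back), a muscle of the scapula (the shoulder blade), gluteus (a muscle of the rump) and intercostal muscle (between the ribs). Each muscle had 1 library, made from total RNA pooled in equal amounts from 3 females of 18 months. There were therefore no replicates, no comparison between muscles could be tested against a spread between animals, and differences are described by their size alone. The 4 tables together held 63845 transcripts at 57988 loci, of which 34877 were intergenic, 26452 lay within an intron of a gene and 2516 overlapped an exon of a gene on the opposite strand. Reads assigned to these transcripts, recovered from the values, came to 2110057 for longissimus thoracis, 1512128 for the scapula muscle, 1136247 for gluteus and 1330224 for intercostal muscle. Values are in FPKM (fragments per kilobase of transcript, scaled to a library total close to its reads in the listed transcripts), and a range in parentheses after a value is its 95% Poisson interval. Sums over groups of transcripts are in reads-per-million (RPM) of the same library total. A read may be counted in more than 1 transcript, so sums and shares of reads may count some reads more than once. The intervals cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules. Whether the counting used strand is not given in the sources used here, so the reads of a gene and those of a transcript on its opposite strand cannot be told apart. Transcripts are named by the gene they overlap or lie within, and the values are those given for the transcript, which for antisense transcripts may include reads of that gene's own messenger RNA.

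The 5 transcripts of highest mean level lay at SNORA53, FHL1, RNase MRP, TRRAP and CNBP. The transcript at SNORA53, a small nucleolar RNA gene, stood at 70876 (70169 to 71589) FPKM in longissimus thoracis, 37510.0 (36899.9 to 38128) in the scapula muscle, 80244 (79201 to 81298) in gluteus and 37933 (37276 to 38598) in intercostal muscle (TCONS_00198593). The transcript opposite FHL1, a LIM domain protein of the sarcomere, stood at 15591 (15433 to 15751) FPKM in longissimus thoracis against 45532 (45210.2 to 45855) in the scapula muscle, 36771 (36433 to 37111) in gluteus and 50061 (49699.8 to 50424) in intercostal muscle (TCONS_00250031). At the gene of RNase MRP, a ribonucleoprotein that cuts the ribosomal RNA precursor, the values were 3598 (3450.2 to 3749.8) FPKM in longissimus thoracis, 31668 (31145 to 32198) in the scapula muscle, 51353 (50575 to 52140.3) in gluteus and 24652 (24158 to 25153) in intercostal muscle. A transcript within an intron of TRRAP, a scaffold of histone acetyltransferase complexes, ran from 11794 FPKM in gluteus to 46299.6 in intercostal muscle. The transcript opposite CNBP, a nucleic acid binding protein mutated in a form of myotonic dystrophy, varied least of these 5, from 18681 FPKM in the scapula muscle to 22312 in intercostal muscle. At lower mean levels, among others and chosen after their values were seen, were transcripts opposite ACTN2, the alpha-actinin of the Z disc, with 7981 FPKM in the scapula muscle and 15571 in intercostal muscle, and opposite KBTBD10, a kelch protein of muscle, with 8451 FPKM in longissimus thoracis and 3514 in the scapula muscle.

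Antisense transcripts were few but carried most of the reads. They made up 5.8% of the listed transcripts in longissimus thoracis, 5.69% in the scapula muscle, 9.07% in gluteus and 7.40% in intercostal muscle. Their share of the reads was 54.1% (Wilson 95% interval 54.0 to 54.2) in longissimus thoracis, 50.7% (50.6 to 50.7) in the scapula muscle, 61.9% (61.8 to 61.9) in gluteus and 55.9% (55.8 to 56.0) in intercostal muscle. The median antisense transcript stood at 55.2, 50.3, 61.3 and 60.3 FPKM in the same order, against 26.6, 23.5, 24.4 and 25.3 for intergenic and 30.8, 25.8, 23.7 and 25.7 for intronic transcripts. The 10 most abundant transcripts held 12.8% of the reads in longissimus thoracis, 14.8% in the scapula muscle and 16.8% in both gluteus and intercostal muscle. The levels could not be set against those of protein-coding genes, which were not analysed here.

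Which transcripts the muscles share was asked next. Listed in every muscle were transcripts opposite MYF6, a myogenic transcription factor, at 604 (557 to 654) FPKM in longissimus thoracis, 379.7 (336 to 428) in the scapula muscle, 488 (429.8 to 552) in gluteus and 652 (590.4 to 719) in intercostal muscle. The same held for the transcript opposite COX7B, a subunit of cytochrome c oxidase, between 259 and 365 FPKM, and opposite CYCS, cytochrome c itself, between 188 and 335 FPKM. Listed in 1 muscle were a transcript opposite PITX1, a homeobox gene of hindlimb identity, at 55.9 (45.1 to 68.5) FPKM in intercostal muscle, and one opposite HOXC11, a homeobox gene of the posterior body, at 38.5 (19.2 to 68.9) FPKM in gluteus. An intronic transcript of RBFOX2, a splicing factor, was listed for longissimus thoracis alone, at 183 (146 to 225) FPKM, and one of FRMD4A, a scaffold protein of cell polarity, for gluteus alone, at 188 (139 to 249) FPKM.

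Longissimus thoracis had 31263 listed transcripts, the scapula muscle 37130, gluteus 20765 and intercostal muscle 26216. All 4 muscles shared 7188 transcripts, which held 79.0% of the reads in longissimus thoracis, 76.1% in the scapula muscle, 87.3% in gluteus and 83.4% in intercostal muscle. Another 7674 were listed in 3 muscles, 14617 in 2 and 34366, or 53.8%, in 1 muscle. Of the antisense transcripts 56.4% were listed in all 4 muscles, compared with 11.3% of the intergenic and 6.87% of the intronic ones. Antisense transcripts also had more reads each, with 54.1% of the longissimus thoracis reads in 5.8% of its transcripts. The classes were not matched on read number, so this contrast does not separate sharing between muscles from ease of detection. Those listed in 1 muscle numbered 13037 for longissimus thoracis, 12206 for the scapula muscle, 3589 for gluteus and 5534 for intercostal muscle. Every listed value was above the detection limit of 0.1 FPKM, so detection and listing are the same here, and a transcript that is not listed is given neither a fold nor an upper limit. Among transcripts with 10 or more reads in at least 1 library, a filter added after seeing the data, 18599 were listed in 1 muscle.

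**Figure D1:**
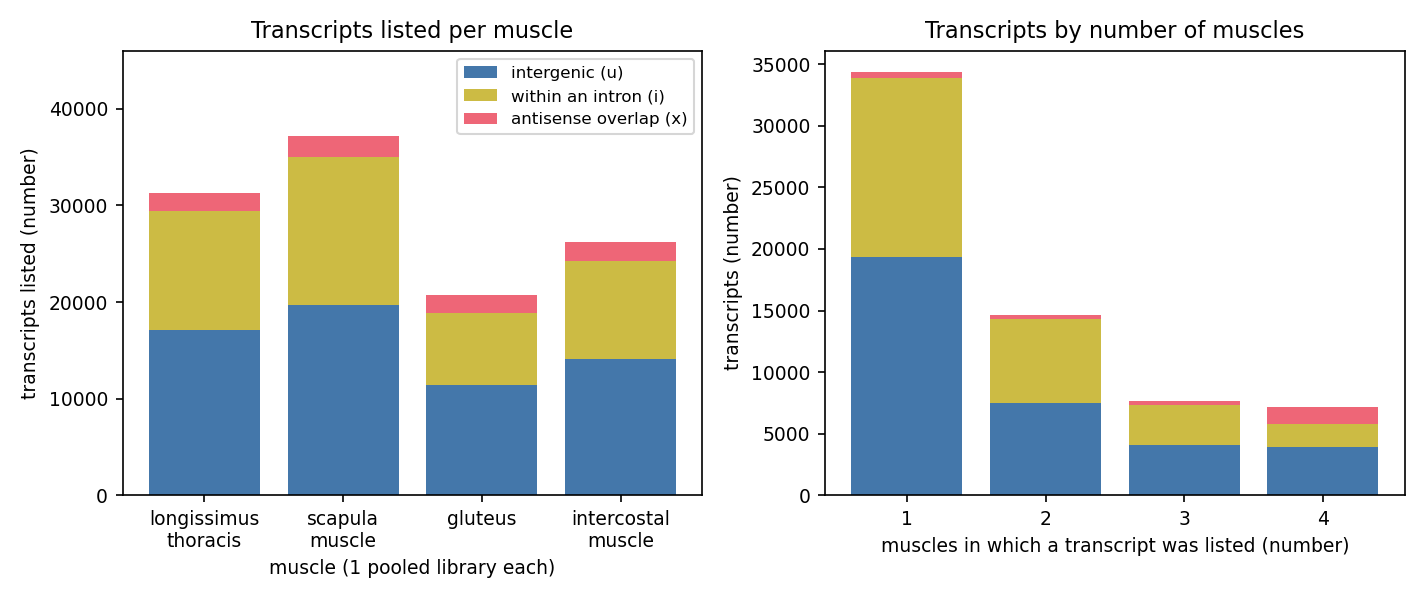
Bars from 0 give the number of transcripts listed for each muscle (left, 1 pooled library each) and the number listed in 1, 2, 3 or 4 muscles (right), with colours for intergenic, intronic and antisense transcripts. The scapula muscle had the most transcripts (37130) and gluteus the fewest (20765), and 34366 were listed in 1 muscle against 7188 in all 4.

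Longissimus thoracis was compared with the other 3 muscles. The 10 lowest ratios among transcripts with a gene symbol, which leaves out intergenic ones, all belonged to antisense transcripts. The transcript opposite CD34, a surface protein of endothelial and progenitor cells, was not listed for longissimus thoracis and stood at 439 (392 to 489.7) FPKM in the scapula muscle, 223 (185 to 267) in gluteus and 182 (151 to 219) in intercostal muscle. Opposite CD81, a tetraspanin, longissimus thoracis had 1 read, 0.624 (0.0158 to 3.47) FPKM, against 512 (471 to 555), 399.8 (358 to 445) and 384 (347 to 425) in the scapula muscle, gluteus and intercostal muscle. Opposite KLHL34, a kelch protein, it had 2 reads, 0.952 (0.115 to 3.44) FPKM, against 649 (609 to 692), 1738 (1661 to 1818) and 738 (692 to 786) in the same order. Not listed there either were the transcripts opposite GAS6, the ligand of the TAM receptor kinases, which lay between 263 and 277 FPKM elsewhere, and opposite COQ4, a protein of coenzyme Q synthesis, between 398 and 527 FPKM. The same was true of CHKB, choline kinase beta, between 179 and 266 FPKM, of SHISA2, between 109 and 1127 FPKM, and of the Cajal body RNA gene SCARNA21, between 270.4 and 805 FPKM.

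Among transcripts with a gene symbol, the 5 highest ratios in longissimus thoracis were intronic, and an intergenic transcript (TCONS_00043063) lay above them. The largest of these intronic ratios belonged to introns of ERGIC2, a protein of the secretory pathway, at 190.2 (152 to 235) FPKM, RBFOX2, AUTS2, a neurodevelopmental gene, at 176 (146 to 211) FPKM, and DTNA, a dystrobrevin of the dystrophin complex, at 176 (125 to 240.4) FPKM. Introns of PICALM, an adaptor of clathrin endocytosis, at 173 FPKM, CAMK2D, a calmodulin-dependent kinase, at 157 FPKM, and WWP1, a ubiquitin ligase, at 149 FPKM also stood among the 10 highest of those with a symbol. In the other 3 muscles these were not listed or reached at most 39.6 FPKM, the scapula value for AUTS2. By the rule of at least 2-fold against the median of the other muscles, 23729 transcripts were higher and 13585 lower in longissimus thoracis, where counting noise alone gave means of 7557 and 5633 over 50 simulated draws. Noise over all transcripts is not like for like in any muscle, since the draws listed a mean of 46775 transcripts in every library against 7188 in the data, which sets above all the number that can be called lower. Among the 7188 transcripts listed in every muscle 1706 were higher and 1765 lower, against 33 and 43 from counting noise. Beyond each of the other muscles there were 17780 higher and 3873 lower, and among the 7188 there were 602 and 937, against 3 and 11 from counting noise. Of 2994 transcripts with 20 or more reads in each of the other 3 libraries, 170, or 5.68%, were not listed for longissimus thoracis. The matching counts were 6 for the scapula muscle, 73 for gluteus and 24 for intercostal muscle.

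The scapula muscle was compared with the other 3 in the same way. The transcript opposite FGF7, a growth factor secreted by mesenchymal cells, stood at 131 (102 to 166) FPKM there and 112 (83.7 to 148) in intercostal muscle, and was not listed for longissimus thoracis or gluteus. An intronic transcript of COL6A3, a chain of type VI collagen, had 154 (114 to 204) FPKM in the scapula muscle and 77.4 (45.9 to 122) in gluteus and was not listed for the other two. Introns of NREP, a gene named for nerve regeneration, reached 345 (286 to 413) FPKM against 43.2 (23.0 to 73.9) in intercostal muscle, and introns of EBF1, a transcription factor of adipocytes and B cells, 179 (138 to 228) against 3.20 (0.0810 to 17.8) in intercostal muscle, the latter from 1 read. An intronic transcript of LAMA4, a laminin of vessel basement membranes, was listed for the scapula muscle alone, at 139.7 (78.2 to 230.5) FPKM. Among antisense transcripts picked after their values were seen, FST, the myostatin antagonist follistatin, stood at 79.2 (65.6 to 94.8) FPKM against at most 21.7 (15.9 to 28.9) elsewhere, and SLC38A1, a glutamine transporter, at 48.6 (37.7 to 61.7) against at most 5.14 (2.47 to 9.46). The lowest ratio kept by the naming rule, which requires the muscle to lie below each of the other 3, belonged to the transcript opposite SRP14, a protein of the signal recognition particle, not listed for the scapula muscle and at 249 (213 to 288) FPKM in longissimus thoracis. Introns of SETD7, a lysine methyltransferase, EPC1, a chromatin protein, and PHKB were the other 3 low ones kept by the rule, each not listed for the scapula muscle. In all, 27566 transcripts were higher and 7187 lower in the scapula muscle, where counting noise over all transcripts gave 7071 and 7771. When each of the other muscles had to be passed by 2-fold the numbers were 16519 and 1109. Within those listed in every muscle 1454 were higher and 1390 lower, against 39 and 76 from counting noise, and beyond each of the others 359 and 482, against 4 and 25.

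In gluteus both antisense and intronic transcripts stood among the 10 highest ratios of transcripts with a gene symbol. The transcript opposite CACUL1, a cullin domain protein of the cell cycle, stood at 456 (394 to 525) FPKM in gluteus and 129.9 (102 to 163) in the scapula muscle, and was not listed for the other two. Opposite MYLK4, a kinase of the myosin light chain kinase family, the values were 174 (140.3 to 213) FPKM in gluteus and 108 (85.6 to 135) in the scapula muscle. Intronic transcripts of PPP3CA, the catalytic subunit of calcineurin, at 146 (103 to 199) FPKM, UBE3A, a ubiquitin ligase, at 149 (104 to 207) FPKM, and CLCN3, a chloride transporter, at 168 (126 to 219.6) FPKM were listed for gluteus alone. Among antisense transcripts picked after their values were seen, that at U8, a small nucleolar RNA of ribosomal RNA processing, had 1352 (1256 to 1453) FPKM in gluteus against at most 179.8 (151 to 213) in another muscle. That at SNORA69 had 349.5 (299 to 407) FPKM against at most 34.9 (21.3 to 54.0), and that opposite CSRNP1, a transcription factor, 117 (98.3 to 137) against at most 8.96 (5.02 to 14.8). Low in gluteus, and not listed there, were introns of SGCD, the delta-sarcoglycan of the muscle membrane, at 117 (83.9 to 159) FPKM in intercostal muscle, and ZBTB16, a zinc finger repressor, at 122 (90.2 to 162) in longissimus thoracis. By the 2-fold rule 11853 transcripts were higher and 15114 lower, where counting noise over all transcripts gave 6696 and 10088. Beyond each of the other muscles there were 6064 and 3254. Within those listed in every muscle 1250 were higher and 1808 lower, against 48 and 127 from counting noise, and beyond each of the others 342 and 799, against 7 and 53.

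Intercostal muscle was set against the other 3 last. Opposite MYL9, a regulatory light chain of smooth muscle, the transcript stood at 1103 (1063 to 1143) FPKM in intercostal muscle, 359.7 (342 to 378) in longissimus thoracis, 306 (286 to 326) in the scapula muscle and 254 (234 to 276) in gluteus. Opposite MYL12B, a light chain of nonmuscle myosin, the values were 269 (247 to 292) FPKM in intercostal muscle and at most 52.5 (43.6 to 62.6) elsewhere, and opposite SCN3B, a sodium channel subunit, 165 (149.6 to 182) and at most 40.1 (34.2 to 46.8). MYL9, MYL12B and SCN3B were picked after their values were seen. By the fixed rule, introns of CEP85L, a centrosomal protein, at 295 (244 to 354) FPKM, IMMP2L, a mitochondrial peptidase, at 191 (146 to 247) FPKM, PLIN4, a lipid droplet protein of adipocytes, at 187 (109 to 299) FPKM, and FYN, a Src family kinase, at 143 (108 to 185) FPKM had ratios among the 10 highest. The transcript opposite IER5, an immediate early gene, had 144 (107 to 189.7) FPKM in intercostal muscle and 22.2 (10.2 to 42.2) in the scapula muscle. Low, and not listed for intercostal muscle, were introns of FKBP5, a glucocorticoid-induced chaperone, at 94.2 (68.2 to 127) FPKM in gluteus, IGFN1, a sarcomeric protein, at 138 (107 to 176) in longissimus thoracis, and MEF2C, a muscle transcription factor, at 149 (120.2 to 182) in longissimus thoracis. Higher transcripts numbered 16830 and lower ones 11404, where counting noise over all transcripts gave 6965 and 9060. Beyond each of the other muscles there were 8837 and 2079. Within those listed in every muscle 1303 were higher and 1492 lower, against 43 and 95 from counting noise, and beyond each of the others 359 and 564, against 6 and 36. Without the longissimus thoracis library, a setting added after seeing the data, the lower counts were 18059 for the scapula muscle, 33846 for gluteus and 28501 for intercostal muscle, since the median of 2 libraries is their mean.

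Pairs of muscles were compared next. Transcripts opposite 3 collagen genes were higher in the scapula and intercostal muscles than in longissimus thoracis and gluteus. Opposite COL3A1, a fibrillar collagen of connective tissue, the transcript stood at 5658 (5561 to 5757) FPKM in the scapula muscle and 2596 (2525 to 2668) in intercostal muscle, against 1156 (1119 to 1194) in longissimus thoracis and 954 (908 to 1003) in gluteus. The values opposite COL5A2, a chain of type V collagen, were 742 (710.5 to 774) and 348 (325 to 372) against 174 (162 to 188) and 152 (135 to 169) FPKM, and those opposite COL12A1, a fibril-associated collagen, 172 and 81.2 against 34.1 and 23.0 FPKM. FBLN2, an extracellular matrix fibulin, had 1236 (1147 to 1330.1) and 804 (728 to 887) against 9.87 (4.26 to 19.5) and 307 (256 to 364) FPKM. RCN1, a calcium-binding protein of the endoplasmic reticulum, had 1965 and 1036 against 227 and 474 FPKM. ITGB5, an integrin, had 747 and 878 against 226 and 269 FPKM, and DPYSL3, a cytoskeletal regulator, 289.8 and 451 against 49.2 and 75.4 FPKM. The smooth muscle myosin gene MYH11 gave 355 and 706 against 159 and 147 FPKM.

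The opposite pattern, higher in longissimus thoracis and gluteus, was seen opposite UCP3, PHKB, HK2 and NR4A3. Opposite UCP3, a mitochondrial carrier of muscle, the values were 3032 (2902 to 3166) FPKM in longissimus thoracis and 3958 (3752 to 4172) in gluteus, against 678 (606 to 756) in the scapula muscle and 406 (347 to 472) in intercostal muscle. Opposite PHKB, a subunit of phosphorylase kinase, which starts glycogen breakdown, they were 3298 (3239 to 3358) and 2193 (2126 to 2261) against 756 (723 to 791) and 644 (611 to 678) FPKM in the same order. HK2, the muscle hexokinase, had 458 and 693 against 218 and 307 FPKM. PDE4D, a cyclic AMP phosphodiesterase, had 1791 and 2186 against 264 and 596 FPKM, and MAPK6, an atypical MAP kinase, 6674 and 7823 against 2266 and 3108 FPKM. DNAJB4, a heat shock protein, had 2255 and 1699 against 212 and 487 FPKM. NR4A3, an exercise-responsive nuclear receptor, had 78.3 (71.3 to 85.8) and 180.2 (165 to 196) against 1.20 (0.389 to 2.80) and 3.57 (1.90 to 6.11) FPKM. COL3A1, UCP3, HK2, MYH11 and NR4A3 belonged to lists fixed before the data were examined. The other genes named for these pairs were chosen after their values were seen. COL5A2 also belonged to such a list, but its antisense transcript was chosen after its values were seen.

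**Figure D2:**
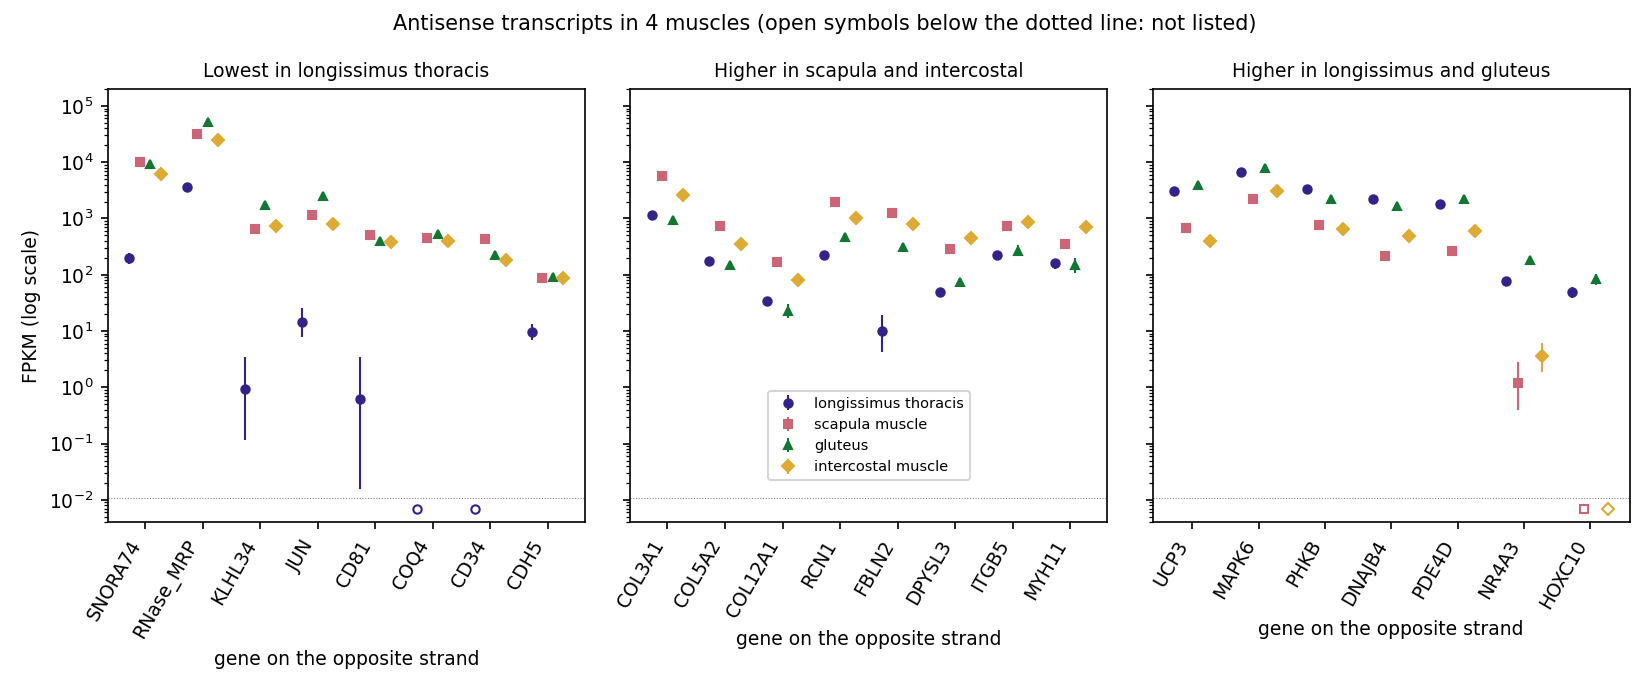
Points give FPKM on a log axis for antisense transcripts, named on the horizontal axis by the gene on the opposite strand, with a colour and symbol per muscle, bars for the 95% Poisson interval and open symbols under the dotted line for transcripts not listed. Opposite COL3A1 the scapula muscle stood at 5658 and gluteus at 954, and opposite UCP3 gluteus stood at 3958 and intercostal muscle at 406.

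Among the 7188 transcripts listed in every muscle, 336 lay at least 2-fold higher in both the scapula and intercostal muscles than in both other muscles, and 333 showed the reverse. Longissimus thoracis and the scapula muscle together exceeded the others in 289 and lay below them in 168, and longissimus thoracis and intercostal muscle in 250 and 208. The largest ratios between pairs of muscles fell on transcripts not listed in the lower muscle. The transcript at SNORA74, a small nucleolar RNA gene (TCONS_00164401), gave the largest ratio of each of the other 3 muscles to longissimus thoracis, at 1326 (1201 to 1460.3) FPKM in the scapula muscle, 1762 (1594 to 1943) in gluteus and 1023 (907 to 1151) in intercostal muscle. An intron of PFKFB3, a regulator of glycolysis, led longissimus thoracis over intercostal muscle, at 263 (231 to 298) FPKM, and an intergenic transcript (TCONS_00043063) led it over gluteus, at 215 (143 to 311) FPKM. Another intergenic transcript (TCONS_00242146) led the scapula over intercostal muscle, at 477 (408 to 554) FPKM. An intron of GHRH, growth hormone-releasing hormone, led intercostal muscle over gluteus, at 298 (241 to 364) FPKM, and one of IQWD1 led gluteus over the scapula muscle, at 255 (194 to 330.2) FPKM. By the 2-fold rule longissimus thoracis was higher than the scapula muscle in 21645 transcripts and lower in 25884. Against gluteus these numbers were 24105 and 12618, and against intercostal muscle 23162 and 17172. The scapula muscle was higher than gluteus in 27147 and lower in 10225, and higher than intercostal muscle in 24583 and lower in 13330. Gluteus was higher than intercostal muscle in 11884 and lower in 17710. Counting noise over all transcripts gave between 7090 and 11308 for each of these 12 counts, with the same limit. Over the 6957 transcripts at 1 FPKM or more in every muscle, longissimus thoracis had 1780 higher and 1847 lower against the scapula muscle. It had 1962 and 1620 against gluteus, and 1827 and 1782 against intercostal muscle. The scapula muscle had 1834 and 1452 against gluteus, and 1468 and 1346 against intercostal muscle. Gluteus had 1476 and 1794 against intercostal muscle.

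Correlations of log2(FPKM + 1) across transcripts, which are not independent replicates, were computed for the 6 pairs of muscles. Over all 63845 transcripts Pearson's r was highest for gluteus and intercostal muscle, 0.26, and lowest for longissimus thoracis and the scapula muscle, −0.18. It was 0.17 for the scapula muscle and gluteus, 0.15 for the scapula and intercostal muscles, 0.061 for longissimus thoracis and gluteus, and −0.025 for longissimus thoracis and intercostal muscle. Spearman's rank correlation was 0.23, −0.19, 0.15, 0.13, 0.041 and −0.044 in the same order. Both sets of values include transcripts not listed in a muscle, entered as 0. Among these were 13037 listed for longissimus thoracis alone and 12206 for the scapula muscle alone. The signs and order of the pairs therefore do not compare levels alone. Over the 6957 transcripts at 1 FPKM or more in every muscle all 6 values of r were positive. They were 0.46 for longissimus thoracis with the scapula muscle, 0.50 with gluteus and 0.48 with intercostal muscle. Between the scapula muscle and gluteus r was then 0.57, between the scapula and intercostal muscles 0.64, and between gluteus and intercostal muscle 0.59.

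Gene lists fixed before the data were examined were compared through the transcripts at their member genes. The random lists were matched on level but not on gene or class, while transcripts of the same gene are not independent of each other. Percentiles may therefore be more extreme than lists matched on gene would give, above all where most members lie at the same gene. Transcripts at slow-twitch fibre genes were lowest in gluteus. Of 9 transcripts at 4 such genes, 6 were at least 2-fold lower there and 0 higher, with a median log2 ratio of −2.37, at percentile 1.37 of 10000 random lists matched on expression. An intronic transcript of TPM3, the slow tropomyosin, stood at 6.34 (3.92 to 9.68) FPKM in gluteus against 60.8 (53.4 to 69.0) in intercostal muscle, and one of MYH7, the slow myosin heavy chain, at 75.2 (48.7 to 111) FPKM in intercostal muscle and 28.9 (14.4 to 51.7) in the scapula muscle without being listed for the other two. With the mean log2 value of the other muscles as reference the gluteus median was −2.19, at percentile 3.12, inside the central 95%. At fast-twitch genes, with 5 transcripts, the percentiles ran from 4.22 in intercostal muscle to 93.8 in the scapula muscle. The fast myosin gene MYH1 had its most abundant intronic transcript at 105 (87.8 to 126) FPKM in the scapula muscle and 40.6 (29.3 to 54.9) in intercostal muscle.

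Transcripts at adipocyte genes were highest in the scapula muscle by the list median. Of 15 transcripts at 5 genes, 11 were higher there and 1 lower, with a median log2 ratio of 5.0 at percentile 98.9. Most were introns of GPAM, an acyltransferase of triglyceride synthesis. By summed reads intercostal muscle lay slightly above, at 117 RPM against 111 in the scapula muscle, 30.5 in longissimus thoracis and 9.03 in gluteus.

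At fibroblast and matrix genes the list median and the summed reads pointed to different muscles. Of 51 transcripts at 11 genes, 31 were higher and 9 lower in longissimus thoracis, with a median log2 ratio of 2.65, above all of the random lists. These were introns, such as those of FBN1, the fibrillin of elastic fibres, with one at 83.6 (62.3 to 110.0) FPKM in longissimus thoracis and not listed elsewhere. Reads at the same 51 transcripts summed to 2603 RPM in longissimus thoracis, 10241 in the scapula muscle, 1876 in gluteus and 4690 in intercostal muscle, where COL3A1 supplied most of them.

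By the list median, transcripts at satellite cell and myogenic genes were high in longissimus thoracis and low in intercostal muscle. Of 25 transcripts at 3 genes, 13 were higher and 1 lower in longissimus thoracis, with a median log2 ratio of 1.11 at percentile 99.4. In intercostal muscle 5 were higher and 12 lower, with a median of −0.47 at percentile 0.89. Most of the 25 lay at MEF2C, while the transcript opposite MYF6, also on this list, had its highest value in intercostal muscle. Summed reads were 631 RPM in longissimus thoracis, 438 in the scapula muscle, 417 in gluteus and 430 in intercostal muscle.

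At immediate early and stress genes the median was lowest in intercostal muscle, at −0.53 and percentile 1.19, with 3 of 15 transcripts higher and 6 lower. With a pseudocount of 0.1 FPKM that median lay at percentile 5.44, and with the mean log2 reference at percentile 10.4, both inside the central 95%. Opposite JUN, a subunit of the AP-1 transcription factor, the values were 14.8 (7.86 to 25.2) FPKM in longissimus thoracis, 1135 (1053 to 1222) in the scapula muscle, 2477 (2335 to 2626) in gluteus and 786 (713 to 864) in intercostal muscle. Reads over the list summed to 311, 584, 1547 and 371 RPM in the same order.

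At position genes the list's medians lay between percentiles 41.3 and 50.6 over 33 transcripts, inside the central 95% in every muscle. Opposite HOXC10, a gene of the posterior trunk and hindlimb, the transcript stood at 48.7 (39.2 to 59.8) FPKM in longissimus thoracis and 82.5 (65.4 to 103) in gluteus and was not listed for the scapula or intercostal muscle. Opposite HOXD4, a gene of the anterior trunk, it stood at 41.1 (29.7 to 55.4) FPKM in the scapula muscle and 7.83 (2.87 to 17.0) in gluteus and was not listed for the other two. Opposite TBX15, a T-box gene of limb and trunk muscle, all 4 muscles had the transcript, at 173 (161 to 186) FPKM in longissimus thoracis, 446 (424 to 470.0) in the scapula muscle, 579 (549 to 610.3) in gluteus and 406 (383 to 430.2) in intercostal muscle.

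The other lists lay inside the central 95% of random lists in every muscle at the main setting. Percentiles ran from 31.4 to 49.8 for 22 transcripts at fatty acid oxidation genes, from 13.5 to 63.3 for 5 at nuclear genes of oxidative phosphorylation and from 45.2 to 95.2 for 57 at atrophy and autophagy genes, where a pseudocount of 0.1 FPKM moved the scapula muscle to percentile 99.3, outside the central 95%. With the mean log2 reference, fatty acid oxidation genes (percentile 1.5), atrophy and autophagy genes (1.92) and imprinted growth genes (1.19) in gluteus and endothelial genes in the scapula muscle (2.20) also lay outside it. Among the atrophy and autophagy genes BNIP3, a mitophagy receptor, had 245 (220.4 to 271) FPKM in longissimus thoracis and between 1176 and 1884 in the other 3. For imprinted growth genes, with 15 transcripts, they ran from 41.4 to 80.9, and for interferon-induced genes, with 5, from 36.5 to 75.3. Among markers of other cell types they ran from 22.5 to 81.9 for 16 endothelial transcripts, from 27.8 to 49.7 for 16 of smooth muscle and pericytes, from 33.0 to 57.4 for 12 of leukocytes and from 25.1 to 96.1 for 9 of nerve and Schwann cells. Opposite CDH5, the cadherin of endothelial junctions, the transcript stood at 9.75 (6.83 to 13.5) FPKM in longissimus thoracis and between 88.3 and 92.8 in the other 3, while 3 intronic transcripts of FLT1, an endothelial receptor kinase, were listed for longissimus thoracis alone, one of them at 118 (90.6 to 150.3) FPKM. Glycolysis genes had 3 transcripts, too few to compare, with HK2 as the most abundant. No transcript lay at the mitochondrially encoded, ribosomal protein, erythroid or known long noncoding RNA genes listed.

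In all, 16 lists in 4 muscles made 64 combinations. The nominal number outside the central 95% is 3.2. It is not the number expected by chance, since many random lists had medians tied at 0 and the ratios of a list share values between muscles. In the data 6 of the 64 lay outside. With the mean log2 value of the other muscles as the reference the number was 12, which adds, besides those given above, fibroblast and matrix genes in gluteus (percentile 0.12) and intercostal muscle (0.455), satellite cell genes in gluteus (0.63) and slow-twitch genes in intercostal muscle (97.7). A percentile describes these libraries only, and a list median of 0 arises where most members were listed neither in the muscle nor in most of the others.

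Set side by side, the RPM at fibroblast and matrix genes in the scapula and intercostal muscles came to 3.33 times those in longissimus thoracis and gluteus, with a 95% interval over resampled transcripts of 0.681 to 3.71. The transcripts opposite COL3A1 and COL5A2 carried this ratio, and without them the other 49 gave 0.791 (0.544 to 1.095). The ratio was 5.77 (2.17 to 23.5) for adipocyte genes, 1.27 (0.941 to 2.96) for smooth muscle, 1.06 (0.277 to 1.49) for endothelial, 1.13 (0.320 to 5.53) for leukocyte, 0.725 (0.499 to 1.51) for nerve and 0.828 (0.527 to 1.01) for satellite cell genes. This grouping of muscles and the omission of both transcripts were chosen after the values were seen. The resampling treats transcripts as independent, which those of the same gene are not, so the intervals may be too narrow. Most adipocyte transcripts were introns of GPAM, so the interval of that list does not show a difference for adipocyte genes as a set.

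**Figure D3:**
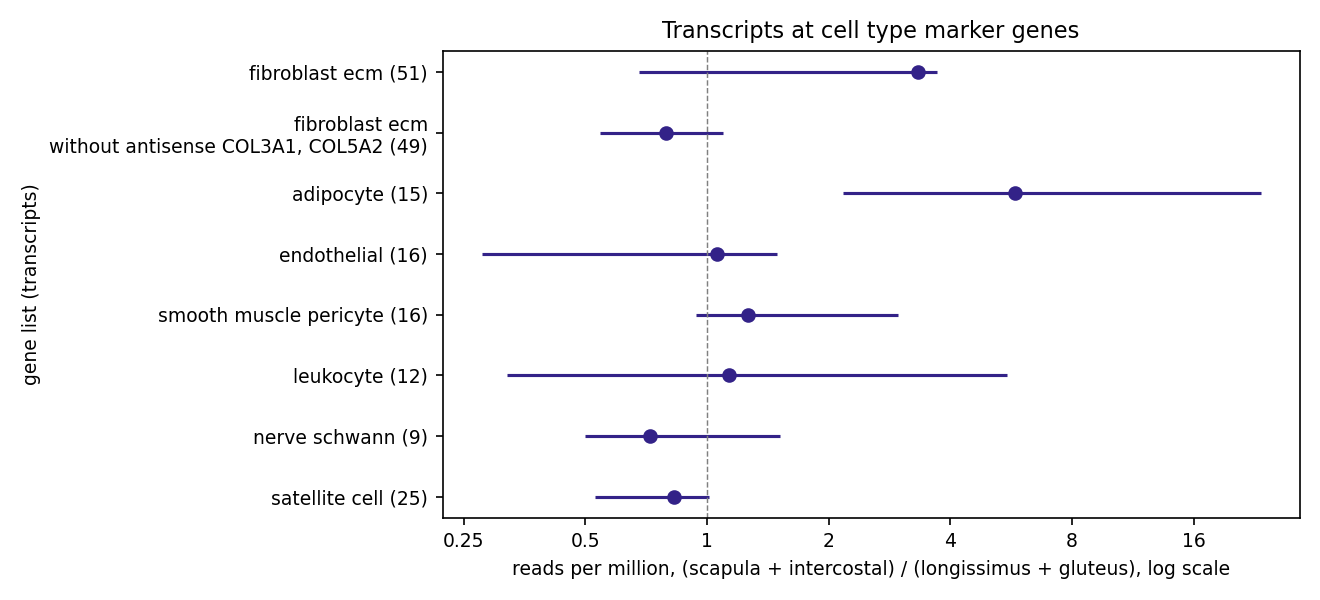
Points give, on a log axis, the ratio of RPM in the scapula and intercostal muscles to those in longissimus thoracis and gluteus for transcripts at each marker list (number of transcripts in parentheses), with bars for the 95% interval over resampled transcripts and a dashed line at a ratio of 1. Fibroblast and matrix genes lay at 3.33 with the transcripts opposite COL3A1 and COL5A2 and at 0.791 without them. Adipocyte genes lay at 5.77 and endothelial genes at 1.06. Transcripts of the same gene are not independent, so the intervals may be too narrow.

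Transcripts at small RNA genes, 128 in all, were a further group with uneven levels. At the 4 transcripts of 5.8S ribosomal RNA genes the sums in RPM were 74.6 in longissimus thoracis, 3985 in the scapula muscle, 6086 in gluteus and 1085 in intercostal muscle. At the pair of transcripts of the signal recognition particle RNA they were 61.4, 2243, 1941 and 2417 in the same order, and at RNase MRP 1051, 9247, 14995 and 7198. A further transcript at SNORA74 (TCONS_00219636) stood at 197 (158 to 242) FPKM in longissimus thoracis against 9977 (9634 to 10329) in the scapula muscle, 9183 (8799 to 9579) in gluteus and 6128 (5841 to 6425) in intercostal muscle. At microRNA genes, with 32 transcripts, the sums were 3980, 4030, 3699 and 3284 RPM, most of it opposite mir-133a-2, and without that transcript 703, 1474, 972 and 1280.1 RPM. The small RNA genes together held 25099 RPM in longissimus thoracis, 34760 in the scapula muscle, 54037 in gluteus and 27419 in intercostal muscle, or, without SNORA53, 7097, 25232, 33654 and 17784 RPM in the same order. These groups were chosen after their values were seen. SNORA74 and the 5.8S ribosomal RNA have several gene copies that can share reads. The 5.8S transcripts TCONS_00148617 and TCONS_00149942 also carry the same locus. TCONS_00148615, TCONS_00148616 and TCONS_00148617 had 53 recovered reads each in longissimus thoracis, and 451, 452 and 451 in intercostal muscle. The sums for 5.8S genes and for all small RNA genes may therefore count the same reads more than once.

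Muscle specificity was summarised by the index tau, which is 0 for equal levels in all muscles and 1 for a transcript found in 1 muscle. Its median was 0.322 for antisense transcripts and 1 for both intergenic and intronic ones. Among transcripts listed in every muscle the medians were 0.139 for antisense, 0.238 for intergenic and 0.283 for intronic transcripts. The classes were not matched on level or read number, so these medians do not separate muscle specificity from read depth. With a pseudocount of 0.1 FPKM the antisense median was 0.222. Antisense transcripts with a low index included that opposite CNBP, and those with the highest included that opposite PITX1.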

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

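No paired analysis was possible because each muscle has 1 library. The planned coding gene comparison and the specificity index matched on level were not run, since coding genes were not analysed here. All values are per transcript, with no separate values per gene to compare. The settings that sum transcripts of a locus, thin the reads, require 10 reads, leave out the longissimus thoracis library or leave out the transcripts opposite COL3A1 and COL5A2 were chosen after the data were seen.

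Most summary values kept their direction and stayed within 1.5 times the reported count or within their interval, 176 in all, and 26 did not. The 176 include settings that could not change a count. A 2-fold call with a pseudocount of 1 FPKM already needs 1 FPKM, so dropping the filter at 1 FPKM had no effect. No listed value lay under 0.1 FPKM, so a detection limit of 0 had none either. The number 176 therefore overstates how many settings were a real check. Rescaling by the median ratio (factors of 1.1 for longissimus thoracis, 1.06 for the scapula muscle, 1.01 for gluteus and 1.06 for intercostal muscle) shifted the median of longissimus thoracis by -0.13 on the log2 scale. It left every count within 1.5 times and the share of higher calls within a percentage point of the reported one.

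Correlations depended most on the set of transcripts. Over those at 1 FPKM or more in every muscle r was 0.46 for longissimus thoracis and the scapula muscle and 0.48 for longissimus thoracis and intercostal muscle, both of the opposite sign to the reported values. It was 0.50 for longissimus thoracis and gluteus, 0.57 for the scapula muscle and gluteus, 0.64 for the scapula and intercostal muscles and 0.59 for gluteus and intercostal muscle. That set leaves out the transcripts not listed in a muscle. With a pseudocount of 0.1 FPKM r was -0.21 for longissimus thoracis and the scapula muscle, 0.041 with gluteus and -0.047 with intercostal muscle, and 0.15, 0.14 and 0.24 for the other pairs in the order above.

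Counts called beyond each other muscle by 2-fold were 3873 lower for longissimus thoracis, 16519 higher and 1109 lower for the scapula muscle, 6064 and 3254 for gluteus, and 8837 and 2079 for intercostal muscle, lower by construction. Without the longissimus thoracis library the lower counts were 18059 for the scapula muscle, 33846 for gluteus and 28501 for intercostal muscle, because the median of 2 libraries is their mean. With 10 or more reads in a library 18599 transcripts were listed in 1 muscle. The median index of antisense transcripts was 0.222 with a pseudocount of 0.1 FPKM, and 12 list and muscle combinations were called with the mean log2 reference. For these last 2 the cause was not tested. The ratio of RPM at fibroblast and matrix genes in the scapula and intercostal muscles to those in longissimus thoracis and gluteus was reversed, from 3.33 to 0.791, without the transcripts opposite COL3A1 and COL5A2, which hold most of the list's reads. With a pseudocount of 0.1 FPKM atrophy and autophagy genes in the scapula muscle were called, at percentile 99.3.

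Of the single transcripts and lists, 314 values stayed as reported, 131 moved, 114 of them transcripts under the pseudocount of 0.1 FPKM, and 3 list calls ended. A true 2-fold difference was called in 58% of simulated cases in longissimus thoracis and in 34% in gluteus. The rule is itself set at 2-fold, on values with a pseudocount, so these shares do not isolate the effect of depth.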

Other observations

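All tests in this part were chosen after the result was seen, except that on introns, whose prediction was written before.

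Transcripts opposite the small nucleolar RNA genes SNORD112 and SNORD113, which lie in the imprinted DLK1 and MEG3 domain, formed a group of 26. They held 332 RPM in longissimus thoracis, 493 in the scapula muscle, 174 in gluteus and 118 in intercostal muscle. One opposite SNORD113 stood at 138 (121 to 157) FPKM in the scapula muscle and 19.2 (12.1 to 28.7) in gluteus. At SNORD107 and SNORD116, genes of another imprinted domain, the sums were 177, 193, 169 and 115 RPM in the same order. Among microRNA genes, the transcript opposite mir-133a-2, whose microRNA is specific to muscle, stood at 926 (904 to 948) FPKM in longissimus thoracis and 566 (545 to 588) in intercostal muscle. That opposite mir-206, also a muscle microRNA, ran from 15.9 (12.7 to 19.7) in longissimus thoracis to 59.7 (50.9 to 69.6) in gluteus, and that opposite let-7c from 58.6 (43.5 to 77.3) in gluteus to 284 (255 to 317) in the scapula muscle.

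Intronic transcripts lay in 5520 host genes. Of these 2136 had 1 intronic transcript, while 212 with 20 or more held 30.8% of all intronic transcripts. PRKG1, a cyclic GMP-dependent kinase, had 213, CMSS1 194, IMMP2L 159 and the zinc finger gene ZBTB20 157. Symbols of Y-linked genes were present although all libraries are labelled female. The transcript opposite DDX3Y stood at 118 (107 to 130.2), 9.23 (5.85 to 13.8), 50.9 (41.1 to 62.4) and 50.1 (41.2 to 60.5) FPKM in longissimus thoracis, scapula muscle, gluteus and intercostal muscle, and that opposite its X-linked relative DDX3X at 1869, 569, 1732 and 799. Introns of UTY held 115, 105, 25.3 and 15.2 RPM in that order, and those of its X-linked relative KDM6A 76.0, 7.28 and 40.6 RPM in longissimus thoracis, scapula muscle and gluteus, with none listed for intercostal muscle. Animals labelled female would not carry Y-linked genes, and the nearest gene names may be loose, so which genes gave these reads is not known.

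The longissimus thoracis library lacked 170 transcripts that had 20 or more reads in each other library, CD34, GAS6 and COQ4 among them. Lower depth is argued against by its scaling total, the read total implied by its FPKM values, which was 1.41 times that of the deepest other library, and a few dominant transcripts by the share of its 10 most abundant ones, 12.8% against at least 14.8% elsewhere. Of the 170, 1.76% lay at small structured RNA genes, so a lower yield there could account for few of them. That share does not weigh against such a yield, since few of the 128 small RNA transcripts had enough reads to enter the set. Together the 128 held 25099 RPM in longissimus thoracis against 34760, 54037 and 27419 in the scapula muscle, gluteus and intercostal muscle. GC content stays open, since 0 of the 170 have a sequence to compute it from. A difference between the muscles themselves, which the design names, also stays open and untested, and it cannot be told apart from other differences in how that library was made.

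More transcripts were listed in 1 muscle than in 2, 3 or 4. Counting error of independent reads is argued against as the whole cause, because 18599 of them had 10 or more reads. Equal rates in the 4 libraries would give 0.0937 if reads were independent. Reads copied by PCR are not independent, so a wider sampling error is not covered by this comparison and stays open. For introns, patchy sampling of genes transcribed in all 4 muscles may contribute. Of the intronic transcripts listed in 1 library, 62.7% had a host gene with an intronic transcript in each other library. With host genes shuffled 100 times the mean was 72.6%, and the lowest and highest shuffles gave 71.6% and 73.7%. Set against that mean, the observed share lies between the bounds set in advance and decides neither way. Differences between muscles stay open.

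Transcripts opposite COL3A1 and COL12A1 were among 336 transcripts at least 2-fold higher in both the scapula and intercostal muscles than in both other muscles. A lower share of muscle fibres in those pools would raise markers of every other cell type alike. The ratio of the scapula and intercostal muscles to longissimus thoracis and gluteus was 1.06 for 16 transcripts at endothelial genes. Its interval over resampled transcripts, 0.277 to 1.49, lay below the bound of 2, which was set after the values were seen. Of these 16 transcripts 15 were intronic, and they lay at 4 genes. Their reads need not follow the share of endothelial cells, so this ratio decides neither way. The ratio at fibroblast genes was 3.33, but 0.791 (0.544 to 1.095) without the transcripts opposite COL3A1 and COL5A2. That at adipocyte genes was 5.77 (2.17 to 23.5). The adipocyte transcripts were all intronic and most lay at GPAM, so this interval may be too narrow. The adipocyte ratio therefore decides neither way on the share of adipocytes. A larger share of adipocytes, more transcription of these collagen genes in fibroblasts and a difference between the muscles themselves stay open and untested. A lower share of muscle fibres stays undecided.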
